A study of Caenorhabditis elegans with 6 samples.

How the data were processed

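Coelomocytes, the scavenger cells in the body cavity of Caenorhabditis elegans, were sorted by fluorescence from dissociated L3 larvae, and their polyadenylated RNA was sequenced. The animals had no germline because they carried the temperature-sensitive glp-4(bn2) allele and were raised at the restrictive temperature, per the labels' protocols. A GFP reporter under the unc-122 promoter, which is active in coelomocytes, marked the cells for sorting. The 6 libraries fall into 2 groups of 3. The control group came from a strain with the reporter alone, and the CHE-1 group came from a second strain that also carried the transgene barIs115, in which the unc-122 promoter drives CHE-1 with the unc-54 3' UTR, beside a red pharyngeal marker under the myo-2 promoter. Libraries were strand-specific and paired-end, per the series' design text.

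The deposited raw table holds estimated counts per gene, already rounded to whole numbers, and Salmon 0.13.1, DESeq2 and the build WBcel235 are named in the submitters' processing notes without a role for each. How transcripts were summed to genes is not given in the sources used here. The 20 largest values all end in 0, as estimates printed with a limited number of digits do. The deposited normalized table holds a signal per gene that equals the raw value divided by 1 factor per library, as the values themselves show, and it lists 12808 of the 21882 genes of the raw table. The normalized table was used only to check this relation, and all tests started from the estimated counts.

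Gene identifiers were given symbols from a gene name table for 19547 genes and from the position of the gene in RefSeq for 2140 more, and 21714 identifiers were found in the WBcel235 annotation, which gave the coordinates. For 53 identifiers the name table and the RefSeq position gave different symbols. Library totals ran from 21353072 to 58325279 counts. A count of 0 was given a floor of 3 counts, which corresponds to a mean of 0.0802 CPM over the control libraries and 0.0803 CPM over the CHE-1 libraries. Folds against a group with a count of 0 in every library were computed against that group mean and are lower bounds, and folds against a group with 1 to 3 counts have an exact 95% counting interval. Intervals and floors cover counting error only, since reads copied by PCR are not independent molecules.

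The groups were compared with the quasi-likelihood test of edgeR 4.0.16 (robust glmQLFit and glmQLFTest, two-sided) in R 4.3.3, with TMM factors and the default count filter by group (minimum count 10, minimum total 15). A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene in the report comes from this test unless another tool is named. Levels are TMM-scaled CPM (counts relative to library size), as mean ± SD of 3 libraries, and log2 fold changes are CHE-1 over control. The standard error (SE) given with a log2 fold change is its absolute value divided by the square root of the F statistic of the test. It is therefore approximate, above all for genes close to 0 counts in a group, such as che-1, where it may be too small. The labels number the libraries but do not say which came from 1 culture or sort, so p-values measure only the spread between these samples, which may be technical. Each library of a pair from the same group differed from the other by far more than sampling noise (chi-square per degree of freedom at least 243), so none was treated as 1 library deposited more than once. This does not show that the libraries came from separate cultures or sorts.

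The comparison, its test, the alternatives and 28 gene lists were fixed before the data were examined. The lists cover CHE-1 target and ASE gustatory neuron genes, pan-neuronal genes, cilia, transcription factors of other neuron identities, coelomocyte identity, endocytic trafficking, lysosome and V-ATPase, canonical histones, histone variants, histone chaperones, chromatin regulators, cell cycle, heat shock, endoplasmic reticulum unfolded protein response, oxidative stress, markers of 7 other cell types or tissues, mitochondrially encoded genes, nuclear respiratory chain, cytosolic ribosomal proteins, neuropeptides, guanylyl cyclase receptors and collagens. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Camera with a correlation estimated per list and the rotation test fry were alternatives. Fry tests whether the genes of a list move, on balance, one way, and does not compare the list with other genes. Members past the threshold were counted after adjustment over all genes and also adjusted over the list alone. For DESeq2 the number of members given for a list is that of members with a count in at least 1 library. Not all of these need have a p-value: over all genes, 10879 of 12913 with a count had one in DESeq2.

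The genes named are che-1, unc-122 and unc-54; the 10 called genes with the largest and the 10 with the smallest log2 fold change among those with no overlap between the groups and a mean CPM of at least 5 in 1 group; and up to 4 members of each list with the smallest p. The other genes were chosen after their values were seen, mostly as further called members of a list, and single alternatives and left-out libraries were not run for them by name.

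Alternatives were other size factors, other count filters, DESeq2 1.42.0, limma-voom, the fit without robust estimation, stricter thresholds, each library left out in turn and a block on consecutive library numbers. A fit of edgeR with adjusted deviances, a fit without the shallowest library of each group and a coelomocyte list without aman-1 were added after seeing the data. The gene test and the list test were tested on simulated data made from the means and sizes of these libraries. Of 8352 genes tested there, 82 were called and 2 of those (2.4%) had not been changed. The gene test called 25% of 100 genes changed 4-fold and 47% of 100 changed 16-fold. Camera put a raised list of 30 genes past the threshold (adjusted p = 2.82e-18) and 0 of 27 unchanged lists. The simulated genes were drawn independently of each other, so this result does not cover lists whose genes vary together. In the data the estimated correlation was 0.78 for ribosomal protein genes and 0.52 for coelomocyte genes.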

Results

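Sorted coelomocytes without the CHE-1 transgene (control) and with it (CHE-1) were profiled in 3 libraries each. CHE-1 is the zinc finger transcription factor that specifies the ASE gustatory neurons, and the series concerns the direct conversion of these scavenger cells to another fate. The control libraries held 57851993, 23062805 and 58325279 counts in total with 9608, 7006 and 11297 genes at a count above 0. The CHE-1 libraries held 21353072, 57860556 and 50101797 counts with 7566, 9559 and 8647 such genes. The libraries varied widely within a group: log2 CPM correlated at 0.69 to 0.83 across genes between control libraries, at 0.66 to 0.73 between CHE-1 libraries and at 0.56 to 0.71 between the groups. The first principal component held 36.2% of the variance and separated the groups. The 10 most abundant genes took 24.5% ± 1.28 of the counts in the control libraries and 15.5% ± 0.752 in the CHE-1 libraries (SD, n = 3 each). The mitochondrially encoded share was 0.401% to 1.08% in the control and 0.753% to 1.08% in the CHE-1 libraries, and the share of the rDNA locus pseudogene rrn-3.56 was 1.58% to 3.87% and 2.57% to 2.99%.

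The comparison asks which genes differ between coelomocytes that express CHE-1 and those that do not. The transgene product was seen first. The gene che-1 (WBGene00000483, chromosome I, 6517529 to 6520918) had 3, 0 and 1 counts in the control libraries and 10744, 50917 and 42227 in the CHE-1 libraries, which is 0.0258 ± 0.0301 against 700.3 ± 185 CPM (SD, n = 3 each). Its log2 fold change was 14.35 (SE 0.54, adjusted p = 1.40e-07 in edgeR's quasi-likelihood test). Gene-level counts do not separate transcripts of the transgene from those of the endogenous gene. The gene unc-122, whose promoter drives both the GFP reporter and the transgene, was at 1668 ± 391 CPM in control and 1360 ± 187 CPM in CHE-1 libraries, a log2 fold change of -0.29 (SE 0.21) that did not pass the test (adjusted p = 0.741). The gene unc-54, which encodes the major myosin heavy chain of body wall muscle and lends its 3' UTR to the transgene, was given 35947 ± 1104 CPM in control and 19987 ± 4189 CPM in CHE-1 libraries (log2 fold change -0.85, SE 0.17, adjusted p = 0.0111). Its counts can include reads of that 3' UTR in the transgene, and whether the GFP reporter carries it too is not given in the sources used here, so the value is not one of the muscle gene alone.

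Of 9112 genes tested, 307 were higher and 154 lower in the CHE-1 libraries. The median log2 fold change was 2.49 for the genes called higher and -1.70 for those called lower, against 0.04 for all tested genes. Among the calls, 304 of the higher and 150 of the lower genes are protein coding, and 27 of the higher genes had no count in any control library while 8 of the lower genes had none in any CHE-1 library. None of the 461 called genes overlapped between the groups, nor did 2131 (23.4%) of the tested genes, where chance gives 10% for 3 against 3. DESeq2 called 685 higher and 412 lower genes, limma-voom 520 and 294, and edgeR with adjusted deviances 697 and 355. DESeq2 called all 307 and 154 of the genes above.

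The highest folds belonged to genes that were close to undetected in control coelomocytes. Among them was gcy-22 (WBGene00001547, chromosome V, 20820118 to 20825062), a receptor-type guanylyl cyclase of the right ASE neuron, with 0.0579 ± 0.0589 CPM in control and 1121 ± 31.4 CPM in CHE-1 libraries (log2 fold change 13.94, SE 0.49, adjusted p = 1.40e-07). ZC84.7 rose from a single count in the controls to 208.1 ± 37.3 CPM, a ratio of 27274 with a counting interval of 4895 to 1077290. D2063.1, F49H12.7 and T05A7.6, with 1, 1 and 2 control counts, rose to 156.6 ± 105, 156.9 ± 23.3 and 243.9 ± 35.4 CPM. Their ratios were 16366 (2937 to 646447), 19255 (3455 to 760560) and 15864 (4391 to 130999). Against control libraries without a count, B0554.7 was at least 505-fold higher, the guanylyl cyclase receptor gene gcy-13 at least 492-fold, the neuropeptide gene nlp-60 at least 461-fold and the chemoreceptor family gene srv-21 at least 439-fold. In the other direction, the lysosomal alpha-mannosidase gene aman-1 (WBGene00018877, chromosome X, 4733095 to 4738592) fell from 5159 ± 1254 to 18.04 ± 17.4 CPM, with a log2 fold change of -8.16 (SE 0.93, adjusted p = 0.00672). Its call was lost without control library 1 (adjusted p = 0.0856), CHE-1 library 1 (0.0696) or CHE-1 library 2 (0.0562), with log2 fold changes between -9.33 and -7.80 when each library was left out. The C-type lectin gene clec-180 fell from 56.98 ± 27.5 to 0.0212 ± 0.0367 CPM (log2 fold change -10.92). In the CHE-1 libraries it had 4 counts, all in library 2, and its log2 fold change ran from -14.17 to -10.31 when each library was left out. ZC21.6, srd-14 and K08D8.6 had no count in the CHE-1 libraries and were at least 499-fold, 448-fold and 349-fold lower. The same held for spe-26 (at least 294-fold), F45D11.2 (253-fold), C23F12.3 (251-fold), B0416.3 (237-fold) and K09E9.7 (222-fold). Each of these 5 calls was lost without 1 of the control libraries: spe-26 without library 1 (adjusted p = 0.0638), C23F12.3 without library 2 (0.159; 0.0744 without the shallowest library of each group), F45D11.2 and B0416.3 without library 3 (0.112 and 0.109), and K09E9.7 without library 2 or 3 (0.0753 and 0.187).

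**Figure D1:**
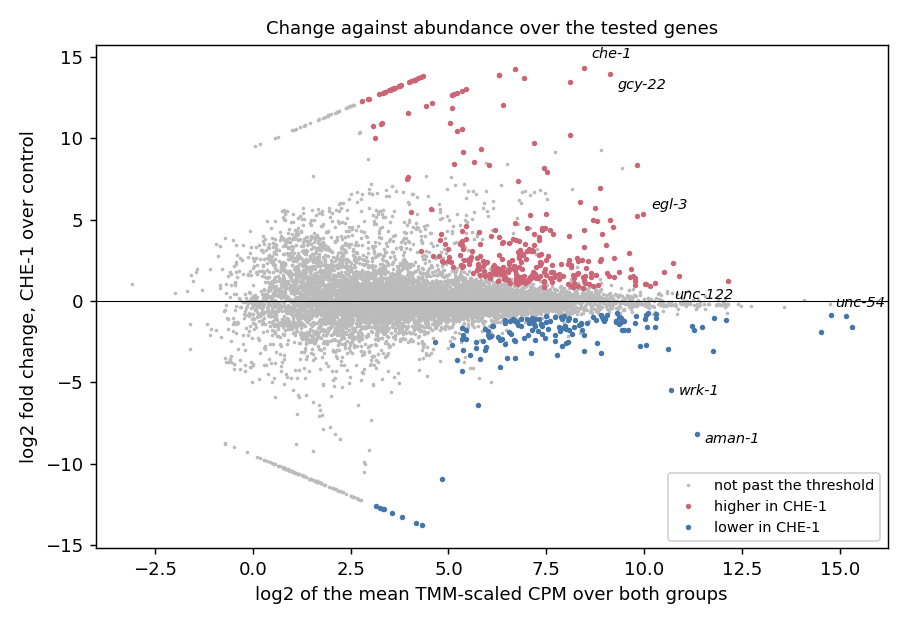
Each point is 1 of the 9112 tested genes, with log2 of its mean TMM-scaled CPM over both groups on the horizontal axis and its log2 fold change, CHE-1 over control, on the vertical axis; red and blue points are the 307 higher and 154 lower genes. The genes che-1 and gcy-22 lie at 14.35 and 13.94, and aman-1 lies at -8.16.

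Genes of the ASE gustatory neurons, the cells that CHE-1 specifies, rose in coelomocytes with the transgene. Of the 15 tested CHE-1 target and ASE genes, 5 were higher and 0 lower, and adjusted over the list alone 8 were higher and 1 lower (camera adjusted p = 6.70e-20; adjusted p = 0.0224 with an estimated correlation; fry adjusted p = 0.00213). The members that rose were the receptor genes gcy-22, gcy-3, gcy-4 and gcy-5 and the homeobox gene ceh-36. The gene gcy-4 reached 169.3 ± 60.1 CPM (log2 fold change 12.02) and gcy-5 reached 74.29 ± 23.5 CPM (10.44, adjusted p = 0.000307). From 1 control count, gcy-3 reached 87.9 ± 13.3 CPM, a ratio of 11221 (2014 to 443242). The gene ceh-36, without a count in the controls, reached 18.8 ± 8.61 CPM (adjusted p = 0.0155). Not past the threshold were gcy-19 (246.3 ± 54.4 CPM against 2.22 ± 3.83, adjusted p = 0.256) and the neuropeptide gene flp-6 (350.4 ± 58.4 against 3.48 ± 4.07, adjusted p = 0.105). Over the whole family of guanylyl cyclase receptors, 5 of 10 tested genes were higher and 0 lower, 6 and 0 adjusted over the list alone (camera adjusted p = 8.37e-28; adjusted p = 0.00837 with an estimated correlation). The median log2 fold change of this family was 8.60, or 7.85 with genes at a count of 0 set to their bound. Every gcy gene of the CHE-1 target and ASE list is also in the list of the receptor family, including gcy-22, gcy-3, gcy-4, gcy-5 and gcy-19. The results of these lists are therefore not independent. These receptors are paralogs, and how the upstream estimate split reads between them was not examined.

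Genes that neurons of every class use also rose, with exceptions. Of 30 pan-neuronal genes, 13 were higher, 2 lower and 15 not past the threshold, and adjusted over the list alone 17 were higher and 3 lower (camera adjusted p = 1.84e-19; adjusted p = 0.0224 with an estimated correlation; fry adjusted p = 0.000804). The SNAP-25 homologue ric-4 rose from 16.43 ± 3.60 to 845.1 ± 64.4 CPM (log2 fold change 5.69, SE 0.26, adjusted p = 4.17e-07). The gene ida-1 rose from 48.96 ± 2.22 to 1126 ± 179 CPM, egl-21 from 34.5 ± 10.8 to 1074 ± 108, sbt-1 from 28.6 ± 14.6 to 862.6 ± 103 and the proprotein convertase egl-3 from 47.99 ± 30.1 to 1962 ± 181 CPM. The synaptic vesicle GTPase rab-3 rose by a log2 fold change of 5.26. The synaptojanin gene unc-26 and the exchange factor gene rgef-1 fell, with log2 fold changes of -1.23 and -1.42. The syntaxin gene unc-64 and the synaptobrevin gene snb-1 did not pass (log2 fold changes 0.39 and 0.29), nor did unc-31, at 124.6 ± 9.77 against 3.23 ± 2.99 CPM (adjusted p = 0.144).

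**Figure D2:**
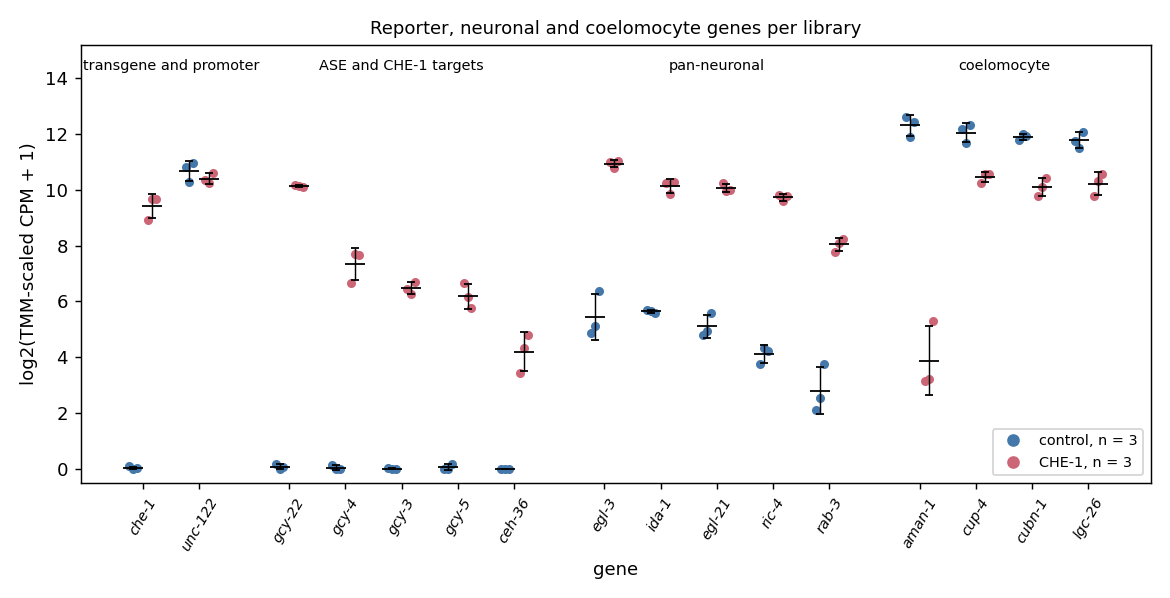
Each point is the log2 of TMM-scaled CPM plus 1 of a gene in 1 library, with control in blue and CHE-1 in red, and lines and bars mark the mean and SD of 3 libraries. The receptor gene gcy-22 is near 0 in the controls and at 1121 ± 31.4 CPM in the CHE-1 libraries, whereas cup-4, cubn-1, lgc-26 and aman-1 are lower in each CHE-1 library than in any control.

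Neuropeptide genes gave 3 higher and 0 lower calls among 70 tested, and 5 and 0 adjusted over the list alone. Those called were nlp-60, flp-16 (57.4 ± 15.9 to 265.9 ± 41.9 CPM, adjusted p = 0.00074) and nlp-21 (log2 fold change 2.77, adjusted p = 0.0185). The call of nlp-21 was lost without control library 1 (adjusted p = 0.0595), control library 3 (0.0639) or CHE-1 library 3 (0.167), and with limma-voom (0.0965). Of 93 neuropeptide genes DESeq2 called 12 higher and 1 lower, with flp-25 (122.5 ± 37.0 against 1.11 ± 1.42 CPM) among them at an adjusted p of 4.05e-09, against 0.0583 in edgeR. The list was past the threshold with camera (adjusted p = 0.0439; adjusted p = 0.896 with an estimated correlation). It was not past without control library 1 (adjusted p = 0.0883), control library 2 (0.0520), CHE-1 library 2 (0.154) or CHE-1 library 3 (0.328), without a count filter (0.102), with DESeq2 (0.263) or with fry (0.471). Of 16 tested genes of sensory cilia and intraflagellar transport, 1 was higher and 0 lower, as adjusted over the list alone 1 and 1, and the list did not pass (adjusted p = 0.414). The higher gene was the kinesin gene klp-11, at 115.1 ± 29.1 against 35.3 ± 6.61 CPM, and its call was lost without control library 3 (adjusted p = 0.0502) or the shallowest library of each group (0.0897). DESeq2 called 3 cilia genes higher and 1 lower of 35, and limma-voom 2 and 1. The cilia gene xbx-1 had no count in the CHE-1 libraries against 13.6 ± 9.47 CPM in control. It was not called by edgeR (adjusted p = 0.0555) and was called lower by DESeq2 (2.85e-09), limma-voom (0.00708) and edgeR with adjusted deviances (0.00550). Of transcription factors of other neuron identities, edgeR and limma-voom called 0 of 8 and DESeq2 0 of 24, with 0, 1 and 0 at an unadjusted p under 0.05. Their list did not pass (adjusted p = 0.636), with a positive median and mean log2 fold change (0.06 and 0.30) and a downward test. Examples are ceh-43 at 2.50 ± 2.28 against 0.0785 ± 0.136 CPM and mab-5 at 17.6 ± 4.89 against 22.9 ± 7.72 CPM.

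Genes of coelomocyte identity fell. Of the 8 tested, 4 were lower and 0 higher, and 5 were lower adjusted over the list alone, with a median log2 fold change of -1.70 (camera adjusted p = 1.12e-10; adjusted p = 0.219 with an estimated correlation; fry adjusted p = 0.0158). The endocytic receptor gene cubn-1 fell from 3810 ± 260 to 1112 ± 244 CPM (log2 fold change -1.78, SE 0.19, adjusted p = 0.000193). The ligand-gated channel genes cup-4 and lgc-26 fell from 4314 ± 942 to 1403 ± 173 and from 3552 ± 712 to 1224 ± 330 CPM. The fourth was aman-1. Summed over the list, CPM went from 19432 ± 2930 to 5458 ± 1027. The coelomocyte regulators ceh-34 and eya-1 had log2 fold changes of -1.94 and -1.95 that did not pass, and unc-122 is given above. For the list coelomocyte identity genes without aman-1, an alternative chosen after seeing the data, camera gave an adjusted p of 1.76e-07 (adjusted p = 0.265 with an estimated correlation).

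Endocytic genes fell in part. Of 44 tested, 6 were lower and 0 higher, and 9 were lower adjusted over the list alone (camera adjusted p = 0.00284; adjusted p = 0.228 with an estimated correlation; fry adjusted p = 0.0146). The clathrin heavy chain gene chc-1 fell from 6034 ± 375 to 2673 ± 313 CPM (log2 fold change -1.17), and the sorting nexin genes snx-1 and snx-3, the recycling gene rme-8, the early endosome GTPase rab-5 and the retromer gene vps-26 fell too, snx-1 from 1076 ± 160 to 311.3 ± 103 CPM. Of 38 lysosome and V-ATPase genes, lmp-1 fell (log2 fold change -1.58, adjusted p = 0.0131) and the Niemann-Pick homologue ncr-1 rose (2.42, adjusted p = 0.0144), a call lost without the shallowest library of each group (0.109). Adjusted over the list alone 2 were higher and 5 lower, and limma-voom called 2 higher and 5 lower. This list did not pass (adjusted p = 0.158) but did without control library 1 (0.0402), and its median and test were downward (-0.32) while its mean was 0.09.

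Of 20 genes of the endoplasmic reticulum unfolded protein response, 3 were lower and 0 higher, and 10 were lower adjusted over the list alone (camera adjusted p = 2.39e-05; adjusted p = 0.328 with an estimated correlation; fry adjusted p = 0.0416). DESeq2 called 9 of them lower. The oxidase gene ero-1 fell from 356.3 ± 40.4 to 63.7 ± 22.1 CPM (log2 fold change -2.48, adjusted p = 0.000296), the BiP gene hsp-3 from 4741 ± 1090 to 2306 ± 253 CPM and the disulfide isomerase gene pdi-6 from 918.6 ± 198 to 438.9 ± 80.9 CPM. The call of pdi-6 was lost without control library 3 (adjusted p = 0.0660) or CHE-1 library 2 (0.0778). For 15 heat shock genes edgeR, DESeq2 and limma-voom called 0, with 0, 3 and 3 at an unadjusted p under 0.05, and edgeR without a count filter called hsp-70 lower (adjusted p = 0.00700). The heat shock list did not pass (adjusted p = 0.414) but did, downward, with limma-voom (0.0157) and without the shallowest library of each group (0.0185). The constitutive chaperone hsp-1 was at 5141 ± 387 against 6299 ± 456 CPM. For 16 oxidative stress and detoxification genes edgeR called 0, with 1 at an unadjusted p under 0.05. DESeq2, with 25 members that had a count, and limma-voom each called 1 lower (list adjusted p = 0.793). That list had a positive median (0.00466), a negative mean (-0.53) and a downward test. The superoxide dismutase gene sod-3 had no count in the CHE-1 libraries against 12.9 ± 10.9 CPM (adjusted p = 0.0748; 1.73e-07 in DESeq2 and 0.0299 in limma-voom).

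The title of the series names depletion of canonical histones. No library used here is labelled as depleted, so the histone values below do not bear on the effect of such a depletion. Of 64 canonical histone genes on the list, 49 were in the table, 33 had a count and 13 were tested. In edgeR 0 of the 13 passed and 1 was at an unadjusted p under 0.05, limma-voom called 0, edgeR with adjusted deviances called 1 higher, and DESeq2 called 1 higher and 3 lower of 33. The list did not pass (camera adjusted p = 0.791), and its summed CPM was 249.6 ± 24.2 in control and 366.7 ± 119.2 in CHE-1 libraries. The most abundant members, his-41 and his-37, were at 188.7 ± 64.5 against 124.9 ± 28.9 and at 131.5 ± 46.8 against 101.4 ± 13.7 CPM (adjusted p = 0.436 and 0.846). Canonical histone transcripts mostly lack a poly(A) tail and their genes are near-identical copies, so these polyA libraries give an uncertain measure of them. Of 14 histone variant and linker histone genes, edgeR called 0 with 3 at an unadjusted p under 0.05. DESeq2 (15 with a count), limma-voom and edgeR with adjusted deviances each called 1 higher. The H3.3 gene his-72 was at 309.3 ± 18.7 against 204.5 ± 23.1 CPM (adjusted p = 0.162; 0.0248 in DESeq2). That list did not pass (adjusted p = 0.414) but did, upward, without CHE-1 library 1 (0.0320), with limma-voom (0.0362) and without the shallowest library of each group (0.00904). For 14 histone chaperone genes edgeR, DESeq2 and limma-voom called 0, with 0, 0 and 1 at an unadjusted p under 0.05. Of cell cycle and replication genes edgeR and limma-voom called 0 of 40 and DESeq2 0 of 44, with 0, 1 and 2 at an unadjusted p under 0.05 (list adjusted p = 0.933 for both lists). Of chromatin regulators tested elsewhere as barriers to fate conversion, edgeR and limma-voom called 0 of 35 and DESeq2 0 of 36, with 1, 2 and 2 at an unadjusted p under 0.05. Their list did not pass (adjusted p = 0.881), with a median and mean log2 fold change just above 0 (0.02 and 0.05) and a downward test. The histone chaperone gene spt-16 was at 246.5 ± 21.5 against 297.0 ± 89.7 CPM, and let-418 at 203.4 ± 25.2 against 301.2 ± 66.8 CPM (adjusted p = 0.271).

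**Figure D3:**
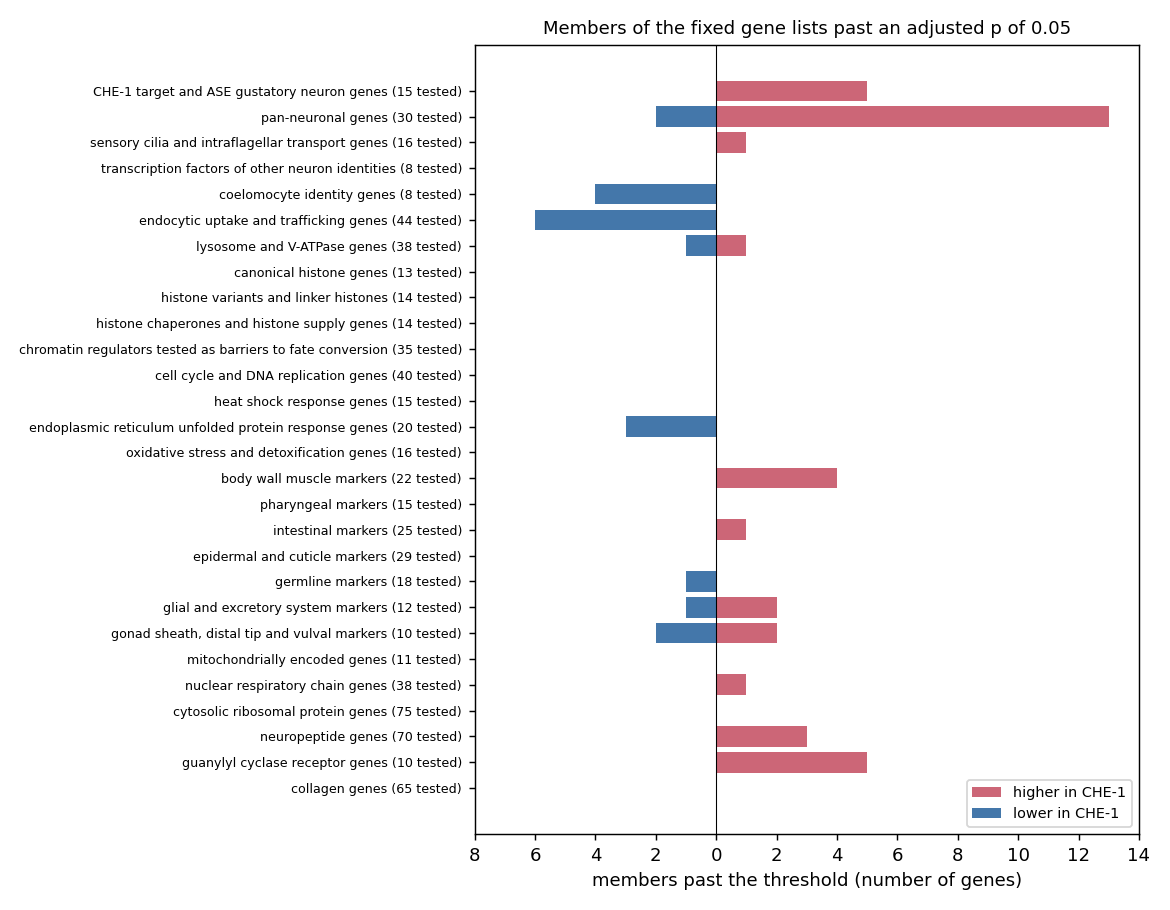
Bars give the number of members of each fixed gene list that were higher (red, to the right) or lower (blue, to the left) in CHE-1 libraries at an adjusted p under 0.05, with the number of tested members beside each name. Pan-neuronal genes had 13 higher and 2 lower, endocytic genes 6 lower, and the 13 tested canonical histones none.

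Markers of other cell types were followed because a sort can hold other cells. Of 22 body wall muscle markers, 4 were higher and 0 lower, over all genes and adjusted over the list alone (camera adjusted p = 0.00284; adjusted p = 0.896 with an estimated correlation; fry adjusted p = 0.248). The list was not past the threshold without control library 3 (adjusted p = 0.0590) or CHE-1 library 2 (0.0715). The troponin T gene mup-2 rose from 165.6 ± 25.8 to 1024 ± 145 CPM, the tropomyosin gene lev-11 from 252.8 ± 70.7 to 814.6 ± 49.4 and the troponin I gene tni-3 from 12.5 ± 6.57 to 155.9 ± 35.8 CPM. The calponin family gene cpn-3 rose by a log2 fold change of 1.12 (adjusted p = 0.0454), a call lost when any library but CHE-1 library 1 was left out (adjusted p = 0.0951 to 0.230) and without the shallowest library of each group (0.0733). The muscle myosin gene myo-3 was at 143.4 ± 80.996 against 87.8 ± 30.96 CPM (adjusted p = 0.607). Of 15 pharyngeal markers edgeR called 0, with 1 at an unadjusted p under 0.05, while DESeq2 called 3 lower of 20 and limma-voom 1 lower of 15. The pharyngeal list did not pass (adjusted p = 0.227) but did, downward, without control library 2 (0.00420), CHE-1 library 1 (0.0107) or the shallowest library of each group (0.000746), without a count filter (0.0329) and with limma-voom (0.0484). The myosin gene myo-2, whose promoter drives the red marker of the transgene, was at 45.8 ± 29.8 against 114.0 ± 108 CPM. Of 25 intestinal markers the galectin gene lec-6 was higher (465.2 ± 164 against 79.9 ± 32.3 CPM, adjusted p = 0.00109) and 0 lower, and 1 and 0 adjusted over the list alone. The intestinal list did not pass (adjusted p = 0.417) but did, upward, without CHE-1 library 1 (0.00163) or the shallowest library of each group (0.00181).

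Of 12 glial and excretory markers 2 were higher and 1 lower, and 2 and 2 adjusted over the list alone (list adjusted p = 0.590). The inositol trisphosphate receptor gene itr-1 rose from 7.57 ± 4.70 to 921.7 ± 189 CPM (log2 fold change 6.94, adjusted p = 0.000739), the glutamate transporter gene glt-1 rose by 2.52, and pros-1 fell by 2.05 on the log2 scale. Of 10 gonad sheath, distal tip and vulval markers 2 were higher and 2 lower, also adjusted over the list alone (list adjusted p = 0.616), with a median of -1.42 and a mean of 0.17. The twist homologue hlh-8 fell from 77.3 ± 15.99 to 3.94 ± 1.27 CPM (adjusted p = 0.000232) and the EGF ligand lin-3 was at least 398-fold higher than in controls without a count. The protease gene gon-1 rose (log2 fold change 1.22, adjusted p = 0.0342) and the FGF receptor gene egl-15 fell (-3.66, adjusted p = 0.0404). The call of gon-1 was lost without control library 2 or 3 or CHE-1 library 2 or 3 (adjusted p = 0.0783 to 0.153) and without the shallowest library of each group (0.0893). That of egl-15 was lost when any library but CHE-1 library 1 was left out (0.0557 to 0.167) and with limma-voom (0.0900). Of 18 germline markers csr-1 was lower (8.51 ± 5.42 against 85.9 ± 38.6 CPM, adjusted p = 0.00755) and 0 higher, and 0 and 1 adjusted over the list alone (list adjusted p = 0.417), with a median of 0.06, a mean of -0.47 and a downward test. Of epidermal and cuticle markers edgeR and limma-voom called 0 of 29 and DESeq2 0 of 37, with 1, 4 and 1 at an unadjusted p under 0.05, and the list did not pass (adjusted p = 0.933), with median and mean both 0.05 and a downward test. Of 65 collagen genes edgeR called 0, with 4 at an unadjusted p under 0.05, while DESeq2 called 1 higher and 2 lower of 110 and limma-voom 5 lower of 65. The collagen list did not pass (adjusted p = 0.0602) but did, downward, without control library 2 (0.00177), CHE-1 library 1 (0.00483) or the shallowest library of each group (2.76e-05) and with limma-voom (0.000945).

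Of 38 nuclear respiratory chain genes ucr-2.2 was higher (170.8 ± 31.6 against 79.2 ± 17.7 CPM, adjusted p = 0.0474) and 0 lower, and 0 adjusted over the list alone (list adjusted p = 0.519). The call of ucr-2.2 was lost when any 1 of the 6 libraries was left out (adjusted p = 0.0593 to 0.160), without the shallowest library of each group (0.243) and without robust estimation (0.0529). Of mitochondrially encoded genes edgeR and limma-voom called 0 of 11 and DESeq2 0 of 12, with 0 at an unadjusted p under 0.05 in each (list adjusted p = 0.879). Of 75 cytosolic ribosomal protein genes edgeR called 0, with 2 at an unadjusted p under 0.05, while DESeq2 called 2 lower and limma-voom 1 lower. That list had 70 members with a negative log2 fold change and a median of -0.18 (camera adjusted p = 0.0264; adjusted p = 0.905 with an estimated correlation), and it was not past the threshold without control library 1 (0.0977), CHE-1 library 2 (0.383) or CHE-1 library 3 (0.283), nor with fry (0.510). The gene rps-2 was at 2152 ± 104.2 against 2971 ± 323 CPM (adjusted p = 0.151; 0.00343 in DESeq2 and 0.00881 in limma-voom).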

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

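The fits of edgeR with adjusted deviances, without the shallowest library of each group and with the coelomocyte list without aman-1 were chosen after seeing the data, and none of the other settings was. The gene che-1 stayed higher at an adjusted p under 0.05 in every fit, with a log2 fold change of 13.995 to 15.39 when each library was left out. None of the 461 called genes was called in the opposite direction in any fit. The counts of higher and lower genes, 307 and 154, were 474 and 255 without a count filter, where 12913 genes were tested, 685 and 412 with DESeq2, 520 and 294 with limma-voom and 697 and 355 with adjusted deviances. They were 188 and 88 at an adjusted p under 0.01, by construction of that threshold, and otherwise the cause was not tested. With 1 library left out the counts were 234 (without CHE-1 library 2) to 347 (without control library 2) and 113 (without control library 3) to 179 (without CHE-1 library 1). A replicate block on consecutive library numbers gave 364 and 205, of which 285 and 145 were among the calls above. The deviations of the libraries so paired correlated at 0.04, -0.07 and 0.04, and not every library correlated best with its own number. This shows no pairing, and a shared culture, sort or day is not excluded by it. With the block the calls of aman-1 (adjusted p = 0.0903), itr-1 (0.102), B0416.3 (0.0563), K09E9.7 (0.0812) and egl-15 (0.0694) were not made, while the lysosome and V-ATPase (0.0434) and collagen lists (0.0271) and the genes hil-3 (0.00109), hsp-70 (0.00919), hsp-16.41 (0.0296), vha-12 (0.00404), vha-13 (0.00776), atf-6 (0.00958) and rps-2 (0.0261) were past the threshold. Without the shallowest library of each group, 2 against 2, 311 and 152 genes were called and 222 and 108 of the 307 and 154 were among them. The lists past the threshold, 9 of 28, were 14 in that fit, 6 (without CHE-1 library 2) to 13 (without CHE-1 library 1) with 1 library left out, 6 with fry and 3 with an estimated correlation, where the coelomocyte list had an adjusted p of 0.219, and of 0.265 without aman-1. Some results not past the threshold in the reported test changed sign, and the cause was not tested. Chromatin regulators turned upward without a count filter (adjusted p = 0.867), with DESeq2 (0.980), limma-voom (0.939) and fry (0.952) and without the shallowest libraries (0.602), and ranged from 0.331 to 0.968 with 1 library left out. Epidermal markers turned upward in the same order at 0.669, 0.748, 0.994, 0.857 and 0.995 and with the block at 0.949, and ranged from 0.588 to 0.958. Cell cycle genes turned downward with a minimum count of 50 (0.984) and ranged from 0.347 to 0.968. Glial markers turned downward and gonad markers upward with limma-voom (0.987 for both), and without the shallowest libraries glial markers (0.591), mitochondrially encoded genes (0.116) and respiratory chain genes (0.937) turned downward. With 1 library left out glial markers ranged from 0.721 to 0.884, mitochondrially encoded genes from 0.215 to 0.994, histone chaperones from 0.639 to 0.968 and heat shock genes from 0.0822 to 0.946, each turning in at least 1 case. The log2 fold change of alr-1 was -0.21 without the shallowest libraries, and that of the mitochondrial gene WBGene00010960 ranged from -0.80 to 0.0586. Depth alone does not set which genes had a count: 5790 genes were at 0 in at least 1 library and at 100 or more in another, and control libraries 1 and 3, with 57851993 and 58325279 counts, held 9608 and 11297 genes. Of the tested genes 39.8% had a count of 0 in at least 1 library, 2117 genes had a count in exactly 1 library, and the common dispersion was 1.51, so a count of 0 bounds counting error only.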

Other observations

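The comparison of the calls between splits of the libraries was fixed before the data were examined, and all other tests here, with their criteria, were chosen after the result was seen. Among the most abundant called genes outside the fixed lists, the following were picked after their values were seen. In CHE-1 libraries the fatty acid and retinol binding protein gene far-1, the most abundant called gene, fell from 60609 ± 7098 to 20078 ± 3205 CPM (log2 fold change -1.59, SE 0.16, adjusted p = 0.000126 in edgeR), and its relative far-2 fell from 1889 ± 448 to 613.5 ± 91.8 CPM. The inositol phosphate synthase gene inos-1 fell from 47465 ± 6468 to 25515 ± 2304 CPM, the adhesion gene dig-1 from 36970 ± 15831 to 9874 ± 3263, the immunoglobulin superfamily gene wrk-1 from 3204 ± 599 to 71.6 ± 30.6 and the endocytic adaptor gene dab-1 from 1832 ± 202 to 275.5 ± 97.2 CPM. The type IV collagen genes let-2 and emb-9 and the SPARC homologue ost-1 rose, emb-9 from 653.6 ± 132 to 2260 ± 530 CPM (adjusted p = 0.000565) and ost-1 from 562.1 ± 56.95 to 2824 ± 676 CPM. The glyceraldehyde-3-phosphate dehydrogenase genes gpd-2 and gpd-3 and the aldolase gene aldo-1 rose by log2 fold changes of 1.43, 1.12 and 1.20, and the phosphoenolpyruvate carboxykinase gene pck-1 went from 51.8 ± 18.4 to 912.5 ± 86.7 CPM (adjusted p = 1.06e-05). The GABA transporter gene snf-11 rose from 47.2 ± 3.89 to 1754 ± 309 CPM (adjusted p = 3.08e-07) and the synaptotagmin gene snt-4 from 182.3 ± 23.6 to 1383 ± 74.4 CPM.

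Gene names were grouped by their class prefix and each of 255 classes was tested in each direction by a one-sided Fisher's exact test with Benjamini-Hochberg adjustment. Among the higher genes the unc class, named for uncoordinated movement, had 18 of 81 tested members (adjusted p = 3.25e-08), including unc-104, unc-13, unc-10 and the ankyrin and spectrin genes unc-44 and unc-70. The gcy class had 5 of 10 (adjusted p = 0.00117). Among the lower genes the lgc class of ligand-gated ion channels had 5 of 21 (adjusted p = 0.00539), which were lgc-23, lgc-24, lgc-25, lgc-26 and lgc-28. Members of a class are often neighbours or paralogs and so are not independent. Called genes also lay next to each other in the order of the tested genes along the chromosomes. There were 19 adjacent pairs of higher genes against a mean of 10.3 in 10000 shuffles (one-sided permutation p = 0.0068), and 10 pairs of lower genes against 2.59 (p = 0.0001, the smallest these shuffles can give). Untested genes can lie between the members of a pair. The shuffles treat all tested genes as independent, which neighbouring paralogs are not.

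In the real split of the 6 libraries 461 genes were called, and in the 9 other splits into 3 and 3 the highest count was 0, so 1 of 10 splits gave as many. Each of the other splits puts libraries of both groups on each side. A difference between the groups then adds to the spread within a side, which lowers the number of calls. The 0 calls there thus do not show what libraries without a difference would give. For the gene lists 3 of 10 splits, the real one included, put at least 9 lists past the threshold, and the highest other split put 10. With 10 splits no share under 0.05 can be reached. The real split thus put no more lists past the threshold than some mixed splits did, in which 0 genes were called. Camera at the preset correlation can therefore put as many lists past the threshold without any called gene. The mixed splits hold the groups in unequal numbers on each side, so part of a group difference stays in them. They cannot decide what the number of lists shows, and that number is not taken as evidence of a difference between the groups.

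The first pattern is the rise of mup-2, lev-11, tni-3 and cpn-3 while none of the 18 other tested muscle markers was called. The others had a median log2 fold change of 0.281 (SD 0.375), so a smaller rise among them is not excluded. More body wall muscle cells in the CHE-1 sorts would bring the other abundant muscle transcripts too, and here the markers point both ways: the median gain of the 18 others was 30.0 CPM against 79.98 (SE 21.4) for cpn-3, the smallest gain of the 4, with 55.6, 31.4 and 39.6 CPM for myo-3, mlc-1 and mlc-2. Of all 22 tested muscle markers 18 had a positive and 4 a negative log2 fold change. The negative ones were tni-1, unc-27, dim-1 and tnt-3. They changed by -9.87 (SE 8.55), -2.79 (SE 45.7), -6.13 (SE 44.2) and -3.45 (SE 17.1) CPM. The actin gene act-4, the paramyosin gene unc-15 and unc-22 gained 579.2 (SE 259.9), 149.5 (SE 157.3) and 123.1 (SE 86.7) CPM. These gains are larger than that of cpn-3 though less than 3 standard errors from 0, so the explanation by more muscle cells stays open. A smaller share of coelomocyte RNA would raise all other cell types alike. The median log2 fold change of 109 markers of 6 other types was 0.141 (bootstrap SE 0.143), which is 0.977 below the smallest of the 4. It falls just short of the difference of 1 first set as a criterion, so the median does not decide. Of the 109, 5 were higher and 4 lower, with itr-1 at 6.94 (SE 0.63) and hlh-8 at -4.29 (SE 0.47). Calls in both directions would argue against an equal rise as the whole source only if the lower genes came from other cells, which was not tested. A listed gene that coelomocytes express would fall with their share. The criterion of calls in both directions was also added after the values were seen, so this explanation is not excluded. The 109 include 18 germline markers, although the animals had no germline. Because all CHE-1 libraries came from 1 strain, a response to the transgene cannot be told apart from another difference between the 2 strains.

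The second pattern is the near loss of aman-1, which had 315589, 89776 and 295925 counts in the control libraries and 173, 516 and 1996 in the CHE-1 libraries, a 286-fold difference of mean CPM. The fall of the other coelomocyte genes is too small for it, since the deepest other member, eya-1, was at -1.95, a difference of 6.20 on the log2 scale. Reads moved to paralogs are argued against by a gain of 89.4 CPM for aman-2 and aman-3 together against 5141 CPM lost. A deletion that reaches the nearest expressed gene upstream is argued against by rpl-25.1, 17299 bp away, at -0.12, and a deletion that removes lon-2, 372 bp away on the other side, by its 6.50 ± 2.38 CPM in the CHE-1 libraries (3.39 ± 4.71 in control), at least 67.3 times the floor in each CHE-1 library. Neither value bears on a deletion of aman-1 that ends short of rpl-25.1 and leaves lon-2 counted. Such a deletion, or a lesion inside aman-1, in the strain with the transgene may be the source. With 1 strain per group and gene-level counts, neither can be told apart from regulation by CHE-1.

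The third pattern is that receptor genes of the right ASE neuron rose while those of the left were hardly counted: of 5 right-type genes edgeR called gcy-3, gcy-4, gcy-5 and gcy-22, and the 4 left-type genes did not pass the count filter and were not tested. The right-type gcy-1 and the left-type gcy-6, gcy-14 and gcy-20 had no count in any of the 6 libraries, the left-type gcy-7 had 193 in CHE-1 library 2 and 19 in control library 3, and the difference between the sides was not tested. Too little counting depth is argued against only for left-type genes at the level of the called right-type genes. The lowest of these, gcy-5, lies with 74.29 CPM 926-fold above the level that a count of 0 allows. The comparison takes called genes only and leaves out gcy-1, so it does not cover left-type genes at lower levels. Other loss of transcripts before counting also stays open. Reads of left-type genes given to right-type paralogs could still contribute and cannot be excluded from gene-level counts, in which 1 left-type gene had counts in the CHE-1 libraries. A right-type bias of CHE-1 targets in these cells is a hypothesis that the data leave open.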
